A study of Homo sapiens with 228 samples.

How the data were processed

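RNA bound by 1 protein at a time was profiled by eCLIP, in which protein is crosslinked to RNA with UV light, the RNA is trimmed with RNase, the protein is immunoprecipitated and the attached RNA is sequenced beside a size-matched input from the same lysate. The labels give 57 experiments with 2 immunoprecipitation and 2 input samples each, 228 samples in all. K562 cells, an erythroleukaemia line, were used for 55 experiments on 53 proteins, with PTBP1 and TIAL1 profiled in 2 experiments each; HepG2 cells, a liver cancer line, were used for CDK9 and PABPN1. The 56 tables used here cover every experiment except PABPN1 in HepG2, which was not analysed here.

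Each table lists the windows of the transcriptome that were enriched in both replicates of an experiment, on human genome build hg38; the submitters' processing notes name STAR as the aligner, and the window caller is not given in the sources used here. Per the file headers, the deposited immunoprecipitation and input values are counts of reads in a window, summed over the replicates of the experiment. The authors' enrichment of a window is the log2 odds ratio of immunoprecipitation over input, given as the lowest, mean and highest of the 2 replicates. The deposited p-value and q-value of a window are the larger of the 2 replicates, and the highest q-value in any table is 0.2. The deposited GC content is a fraction of the bases of the window. Windows are 1 to 100 bases wide and carry a feature type and a gene name; 2.93% of windows carry several joined gene names. Of 12689 gene names, 11284 match a symbol of the RefSeq annotation of the reference genome, and names are kept as deposited. Coordinates are reported counted from 1.

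The tables hold 2783992 windows, 1123722 of them distinct. Windows per experiment run from 615 (LARS) to 272069 (CDC40), with a median of 27048. The immunoprecipitation reads in windows run from 142302 (PSMD4) to 20413448 (UPF1) and the input reads from 20120 (CDK9) to 2347083 (EIF2S1). These are reads in enriched windows and not library totals, so they do not measure sequencing depth, and a gene without a window is one where none was detectable at the depth of that experiment. Shares of windows or reads in a single experiment carry 95% Wilson intervals, which cover counting error only. The widest is 7.66 percentage points for a region's share of windows and 0.415 points for a read share quoted for a single experiment; p-values instead measure the spread between proteins.

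Before the data were examined, each protein was put in 1 class from general knowledge of its function: 15 nuclear RNA processing proteins, 10 translation initiation factors, 9 other cytoplasmic mRNA proteins, 4 AU- or U-rich element binders, 3 nucleolar proteins, 2 chromatin proteins and 10 others, all in K562. The same was done for 19 gene lists, 18 pairs of related proteins, the tests, the rules for naming genes and most alternatives. The comparison of the lists between initiation factors and other cytoplasmic mRNA proteins was not among these tests. The nuclear class was compared with the 19 initiation and cytoplasmic mRNA proteins together, called the cytoplasmic side below, and the initiation factors with the 9 other cytoplasmic mRNA proteins. Repeat experiments of a protein were averaged, so n is the number of proteins. Chromatin, nucleolar, AU-rich and other proteins entered the overlaps and the per-experiment values but not these contrasts. The window tiling of the HepG2 table differs from that of K562, and CDK9 was left out of the comparisons.

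Windows were assigned to CDS, 5' UTR, 3' UTR, intron (windows next to or near splice sites included) and noncoding exon; a further category, other mRNA exon, counts in the total and was not tested. The percent of an experiment's windows in each region, or in the genes of each list, was compared by a permutation test of the difference of class means, with 100000 resamples for the larger contrast and every arrangement (exact) for the smaller. Benjamini-Hochberg adjustment ran over the 5 regions or the 19 lists, and adjusted p-values under 0.05 are called. Tested on simulated data with the same class sizes, 400 features each, the test called 5% of features without a difference and 79.5% with a shift of 1 SD in the larger contrast, and 3.75% and 54% in the smaller. The simulated values were normal with the same spread in both classes. Real shares often differed in spread between classes, so these rates may not hold for them.

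Genes were tested on their number of windows per protein with the edgeR 4.0.16 quasi-likelihood test, with the total windows of a protein as library size and no further scaling. Genes needed 10 windows in all and windows in 5 proteins, and repeat experiments were summed. The older quasi-dispersion of edgeR was set aside for the newer one on simulated data, after its count of calls in the real data had been seen: at a simulated log2 fold of 4, 21.2% of its calls were false, against 7.65% with the newer one. With the newer one, simulated data without change gave 0 calls among 10069 genes (the older gave 9), and 9% of 200 changed genes were recovered at a log2 fold of 2, 53% at 3 and 78.5% at 4. Fold changes were named for the 12 genes with the largest change in each direction among those called that had windows in at least 50% of the proteins of the higher class. For genes with 0 windows in a class, the ratio of the gene's shares of all windows was bounded with a floor of 3 windows over the class; for 1 to 3 windows the ratio is given with an exact counting interval.

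The overlap of window sets is the number of shared windows (same coordinates and strand) over that expected from the sizes of both sets among the 1123453 windows found in any K562 experiment. Related pairs were tested by permuting protein labels, and so was the number of proteins with a window on their own gene. Ribosomal DNA windows are those of the 45S repeats on chromosome 21, split by the RefSeq positions of 18S, 5.8S and 28S rRNA. For the 10 experiments with most windows and the proteins with a known motif, 23 experiments in all, the window with the highest enrichment in the authors' deposited table was looked up among windows with at least 50 immunoprecipitation reads. The leading gene of an experiment is the one with most immunoprecipitation reads, and of each list the 3 members with windows in most proteins are named. A planned motif test needs the genome sequence and was not run.

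Alternatives were a q-value under 0.05, a lowest log2 enrichment of at least 2, leaving out windows found in more than 10 experiments, weighting by reads, minimum window numbers of 1000 or 2000, other denominators, exonic windows only, counting each experiment on its own, TMM scaling, DESeq2 1.42.0, no filter, reads in place of windows, thinning to 500 windows, other overlap measures and leaving out each protein in turn. Chosen after seeing the data were the alternatives without ribosomal DNA, without YTHDF2, PDCD4 and CNOT3, and with the older quasi-dispersion. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, with seed 1.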

Results

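The experiments cover RNA-binding proteins from splicing to translation, and the comparisons ask where on transcripts, and on which transcripts, proteins of different compartments leave enriched windows. A window here is a stretch of at most 100 bases that was enriched over size-matched input in both replicates.

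Nuclear processing proteins on average left most of their windows in introns, and cytoplasmic proteins left theirs in exons, with exceptions on both sides. PTBP1 (92.2% of windows in introns), USP39 (91.5%) and SFPQ (91.1%) were almost wholly intronic, whereas the 3' UTR held 63.7% of the windows of UPF1, 61.6% of PABPC1 and 51.8% of IGF2BP1. USP10, UBAP2L and EIF2B5 had 75.0%, 72.8% and 73.1% of their windows in coding sequence. Not every nuclear protein was intronic: the export factor THOC4 had 8.46% of windows in introns and 59.1% in coding sequence, DDX41 and RBM15 had 67.1% and 60.4% in coding sequence, and introns held 40.2% for NCBP1 and 39.1% for YTHDC1. In the other direction, YTHDF2 (69.2%), PDCD4 (79.4%) and CNOT3 (73.8%) of the cytoplasmic side were mostly intronic, and introns were the leading region of EIF2S2 (50.2%), EIF2S1 (49.5%) and EIF3E (40.8%). Ribosomal DNA windows keep their deposited feature type in these shares, and were 24.5% of the windows of EIF2S2 and 11.5% of EIF2S1. How many of them count as intron was not separated, so these shares need not be introns of mRNA precursors.

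**Figure D1:**
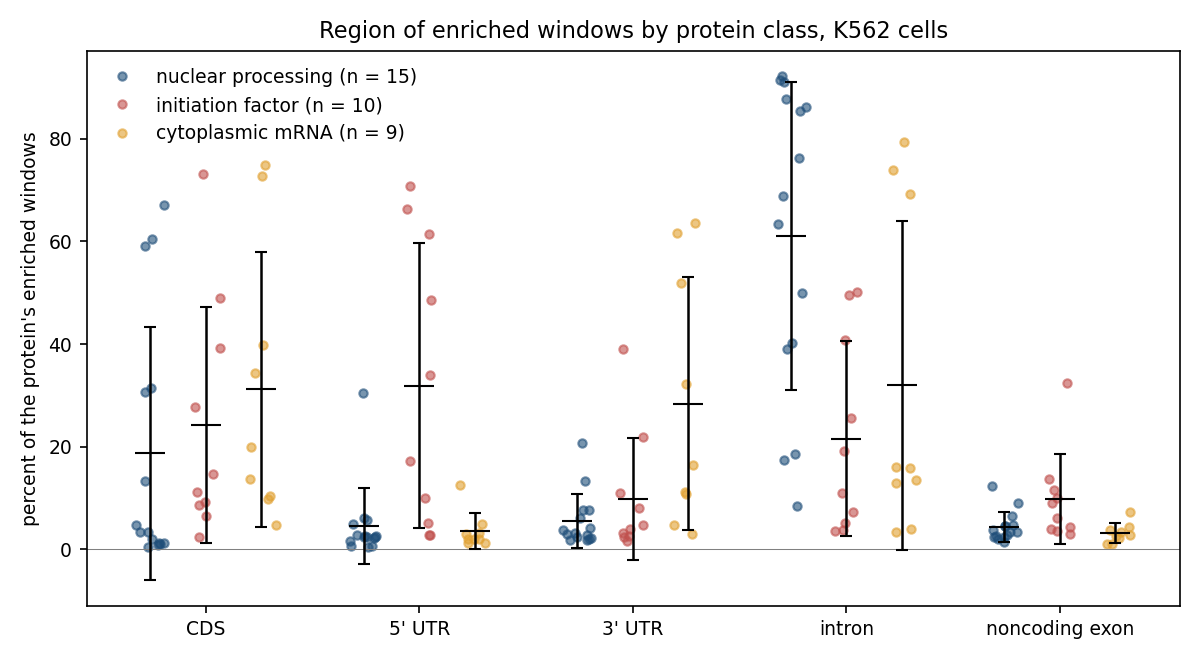
Percent of enriched windows in each transcript region, by protein and class.

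Introns held 61.1% ± 29.96% (mean ± SD) of the windows of the 15 nuclear proteins and 26.5% ± 25.8% of those of the 19 cytoplasmic proteins, a difference of 34.6 percentage points (permutation p = 0.00164, adjusted p = 0.0082); 12 of 15 nuclear proteins were above the cytoplasmic mean. The 3' UTR held 5.52% ± 5.26% against 18.6% ± 20.8% (permutation p = 0.0200, adjusted p = 0.0499; 11 of 19 cytoplasmic proteins above the nuclear mean). That call is borderline: leaving out any of 19 of the 34 proteins ended it, with adjusted p from 0.0546 to 0.0722. These were CDC40, DDX41, DDX5, EIF2B4, EIF4G2, FUS, IGF2BP1, LARP1, PABPC1, PTBP1, QKI, RBM10, RBM15, RBM5, SFPQ, TAF15, UPF1, USP10 and USP39. The 5' UTR held 4.58% ± 7.39% against 18.5% ± 24.6% and missed the threshold (adjusted p = 0.0702), but passed it without the cap-binding protein NCBP1, whose 5' UTR share was 30.6% (adjusted p = 0.0381). Coding sequence (18.7% against 27.5%) and noncoding exons (4.395% against 6.64%) were not called (both adjusted p = 0.306). When windows were weighted by their reads, the intron difference was 8.81 points (adjusted p = 0.502), and 26.4 points (adjusted p = 0.0333) once ribosomal DNA was also left out.

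Within the cytoplasmic side, several initiation factors concentrated on the 5' UTR, where ribosomes are recruited. The eIF3 subunits EIF3B (70.8% of windows) and EIF3C (66.4%) led, with EIF1 (61.5%), EIF4H (48.6%) and EIF3E (33.9%) behind them. EIF2S2 (2.75%), EIF4G2 (2.89%), EIF2B5 (5.12%) and EIF2B4 (9.96%) were lower. Among the other cytoplasmic mRNA proteins LARP1 was highest, at 12.5%. The class means were 31.9% ± 27.8% for 10 initiation factors and 3.59% ± 3.54% for 9 other proteins (exact permutation p = 0.00723, adjusted p = 0.0259; 8 of 10 above the mean of the others). With windows weighted by their reads the difference fell from 28.3 to 7.23 points and was not called (exact permutation, adjusted p = 0.455). Noncoding exons were also higher, at 9.74% ± 8.78% against 3.19% ± 1.93% (exact permutation p = 0.0103, adjusted p = 0.0259; 9 of 10), with EIF2S2 at 32.4%. That call ended, at 3.23 points, in experiments of at least 1000 windows, which leave out EIF2S1 and EIF2S2 (exact permutation, adjusted p = 0.0656), and at 3.13 points with read weighting (0.455). Leaving out IGF2BP1, PABPC1, UBAP2L, USP10 or YTHDF2 ended both calls, with adjusted p (exact permutation) up to 0.0567 for the 5' UTR and 0.0635 for noncoding exons. The 3' UTR was lower in initiation factors, 9.87% ± 11.9% against 28.4% ± 24.7%, without passing (exact permutation, adjusted p = 0.0846); it passed without CNOT3, EIF4G2 or PDCD4, with adjusted p of 0.0466, 0.0313 and 0.0420 in the exact permutation test. Coding sequence (24.2% against 31.2%, adjusted p = 0.547) and introns (21.6% against 32.0%, adjusted p = 0.490) were not called in the same exact test.

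Some proteins stood out at the borders of introns and coding sequences. RBM5 had 34.02% (95% interval 33.4% to 34.6%) of its windows next to a 3' splice site, its paralogue RBM10 24.2% and the spliceosome protein CDC40 13.1%, against a median of 0.896% over the 56 experiments. Next to 5' splice sites TIAL1 led with 18.6% and 14.3% in its separate experiments, with CDC40 at 15.6% (median 1.71%). Start codons were most frequent for EIF4H, at 16.4% (15.9% to 16.8%) of windows, EIF3B (7.79%) and NCBP1 (7.12%), against a median of 0.832%. Stop codons led for USP10 (6.63%), LARP1 (6.35%) and PABPC1 (6.11%), against a median of 0.862%. These shares are values with no test.

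**Figure D2:**
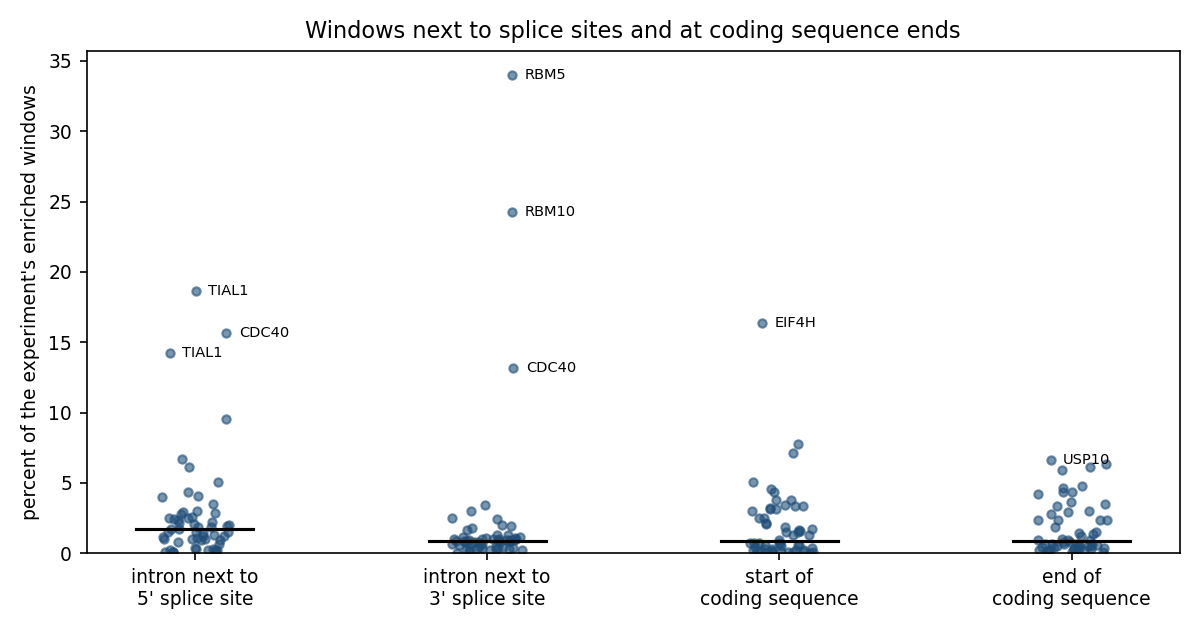
Percent of windows next to splice sites and at the ends of coding sequences, by experiment.

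By gene list, cytoplasmic proteins favoured mRNAs for the respiratory chain, for translation factors and for the integrated stress response. Windows in nuclear-encoded OXPHOS genes were led by NDUFS7 (windows in 19 of 19 cytoplasmic proteins), ATP5F1A (16) and UQCRC2 (15), translation factors by EIF4G2 (19), EIF4A1 (18) and EIF2AK1 (17; a kinase that the list's name pattern took in), and stress-response mRNAs with upstream reading frames by EPRS1 (15), ATF4 (15) and PPP1R15B (14). Nuclear proteins also had windows in these genes. Of 15 nuclear proteins, the counts in the same order were 14, 7 and 11 for OXPHOS, and 13, 13 and 14 for translation factors. For the stress-response mRNAs they were 10, 9 and 5. OXPHOS genes held 0.307% ± 0.204% of the windows of nuclear and 1.06% ± 0.634% of those of cytoplasmic proteins (permutation p = 0.00011, adjusted p = 0.00209; 16 of 19 above the nuclear mean). Translation factors held 0.620% ± 0.377% and 1.38% ± 0.871% (permutation p = 0.00211, adjusted p = 0.0153; 15 of 19), and the stress-response list 0.0719% ± 0.0683% and 0.180% ± 0.115% (permutation p = 0.00241, adjusted p = 0.0153; 17 of 19). These calls held without any single protein, but with windows weighted by their reads only OXPHOS kept its call (adjusted permutation p = 0.0441), and translation factors (0.126) and the stress-response list (0.273) lost theirs. The stress-response list also lost its call with q under 0.05 (0.0718) and translation factors with exonic windows only (0.0771).

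**Figure D3:**
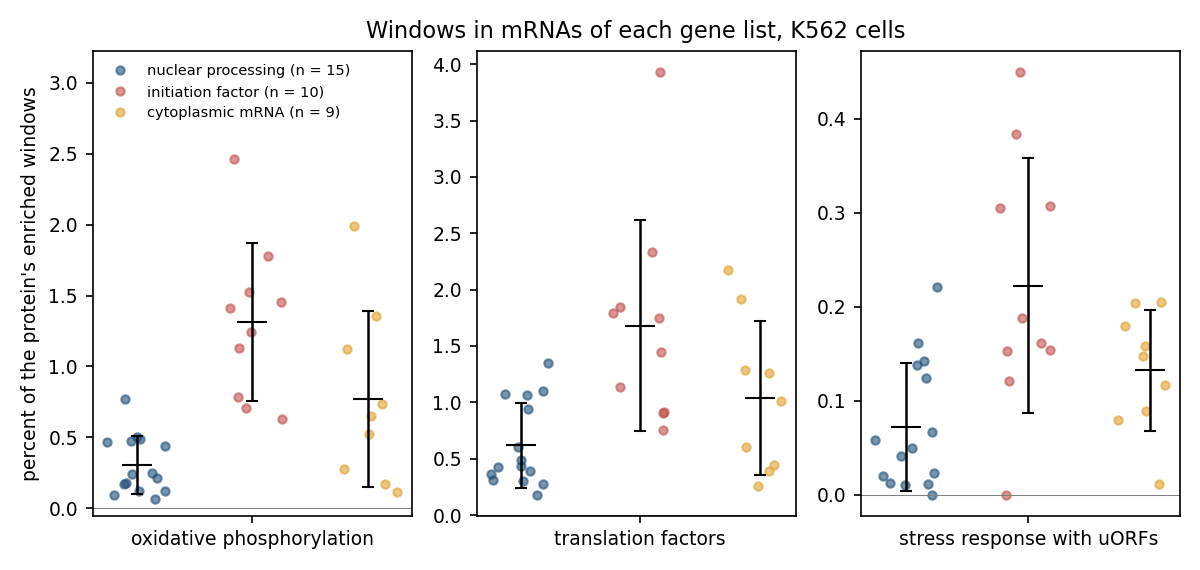
Percent of windows in the genes of each list, nuclear against cytoplasmic proteins.

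The other 16 lists did not pass. Means for nuclear and cytoplasmic proteins, with adjusted permutation p, were 0.588% and 1.82% for ribosomal protein mRNAs (0.0683), 0.276% and 0.569% for other TOP mRNAs (0.0683), 0.135% and 0.330% for AU-rich immediate early mRNAs (0.0683), 0.279% and 0.492% for the proteasome (0.0719), and 0.102% and 0.190% for IGF2BP targets (0.129). Histone mRNAs held 0.343% and 1.18% (0.166), snoRNAs and their host genes 0.232% and 2.58% (0.2004), mitochondrially encoded transcripts 0.173% and 0.446% (0.389) and ribosomal RNA genes by name 0.00572% and 0.0252% (0.226). For nuclear long noncoding RNAs the means were 0.556% and 0.662% (0.760), for splicing regulators 1.26% and 1.39% (0.734), for erythroid genes 0.501% and 0.464% (0.760), for snRNAs 0.308% and 0.320% (0.976) and for 7SK, 7SL and similar RNAs 0.151% and 0.1203% (0.973). The snRNA and 7SK lists consist mostly of pseudogenes. The hepatocyte list matched APOE only among the windows of these proteins, 0.000177% and 0.00491% (0.0719), and the tRNA list matched only TRNAU1AP and TRG-AS1 among its leading members, which are not tRNAs, 0.0122% and 0.00563% (0.166). Leaving out 1 protein brought some lists under the threshold, with adjusted permutation p from 0.0290 to 0.0488. Without CNOT3 these were the other TOP, AU-rich, ribosomal protein, hepatocyte and tRNA lists, and without NCBP1 the other TOP, AU-rich, ribosomal protein, IGF2BP and histone lists. Without UBAP2L or UPF1 they were the other TOP, AU-rich, ribosomal protein and hepatocyte lists, without PDCD4 other TOP, ribosomal protein, hepatocyte and proteasome, without YTHDF2 other TOP, ribosomal protein and proteasome, without EIF2S2 AU-rich and proteasome, and without YTHDC1 AU-rich. Between initiation factors and other cytoplasmic mRNA proteins, histone mRNAs (2.01% against 0.266%) and snRNAs (0.575% against 0.0368%) were higher in initiation factors, both with an adjusted exact permutation p of 0.0469. This comparison of the lists was not among the planned tests. No alternative was run for it, and no protein was left out in turn. The highest histone share of an initiation factor was 8.31%, against a median of 1.53%.

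Gene by gene, the genes called for nuclear proteins were longer and more often noncoding than genes not called. Their windows lay mostly in introns, with a median of 66.1% per gene, against 7.69% for genes called for cytoplasmic proteins. The latter were mostly short mRNAs. The long noncoding RNA PURPL (chromosome 5, 27217714 to 27495948) had 102 windows of nuclear and 0 of cytoplasmic proteins, at least 20.03-fold more per window found. Among mRNAs of the cytoplasmic side were COX7C of the respiratory chain, the tubulin TUBA1A, the embryonic globin HBZ and the cancer-testis gene MAGEC2. Of 10290 genes tested with edgeR, 437 had more windows of nuclear (280 without PTBP1) and 1203 more windows of cytoplasmic proteins. A span was found in the RefSeq annotation for 360 of the 437 nuclear calls, 1144 of the 1203 cytoplasmic calls and 8217 of the 8650 genes not called. Among these the median span was 91.2 kb, 10.4 kb and 33.2 kb. Long noncoding RNAs made up 100 of the 437, 44 of the 1203 and 491 of the 8650, and 306 of the 437 were protein coding. These differences of span and gene type were not tested. Across genes, which are not independent replicates, the log2 fold correlated with span (Spearman's rho 0.458) and with the percent of intronic windows (0.560). That percent comes from the same windows as the fold, so its correlation partly restates the region result. The split between directions depends on scaling: the median log2 fold of all genes was -0.32 here and -0.04 with TMM, where 663 genes were higher with nuclear and 719 with cytoplasmic proteins. DESeq2 called 197 and 102 genes, and edgeR on reads in place of windows 448 and 346, so the majority turned.

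**Figure D4:**
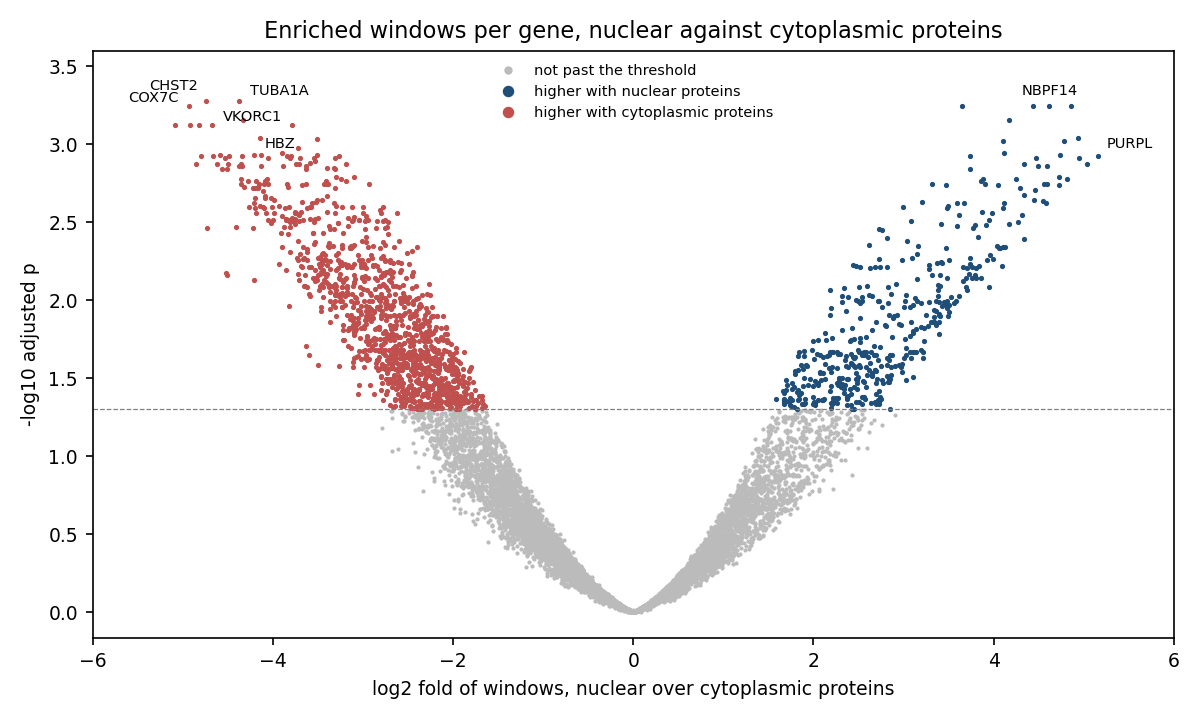
Fold change of windows per gene, nuclear over cytoplasmic proteins, against the adjusted p of the edgeR test on a log scale, with some of the named genes marked.

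Most of the 12 nuclear genes named by the rule lacked the cytoplasmic windows for a well-bounded fold. Beside PURPL, SRGAP2D (82 and 0 windows), PDXDC2P-NPIPB14P (64 and 0) and TPTE2P2 (62 and 0) were at least 16.1-, 12.6- and 12.2-fold higher per window found. With 1 to 3 cytoplasmic windows, the ratios of pooled windows, with intervals that leave out the spread between proteins, were 121 (41.3 to 589) for ENSG00000286163, 96.0 (17.0 to 3815) for SLCO1A2, 81.9 (14.5 to 3257) for RFX3-DT, 60.7 (16.6 to 504.3) for UBE2Q2P1, 53.6 (18.1 to 262) for LINC01572 and 52.4 (9.17 to 2094) for L3HYPDH. For ENSG00000286163, whose 617 nuclear windows are spread unevenly over 8 proteins, the fitted log2 fold was 4.78 with edgeR and 3.37 with DESeq2, which did not call it (adjusted p = 0.183); DESeq2 gave no adjusted p for PURPL, SRGAP2D, PDXDC2P-NPIPB14P, TPTE2P2 and L3HYPDH. The log2 fold was 4.62 (SE 0.85, edgeR adjusted p = 0.000566) for NBPF14, with 386 and 7 windows, and 4.44 (SE 0.84, adjusted p = 0.000566) for ENSG00000230258, with 325 and 6. NBPF14, SRGAP2D, TPTE2P2, UBE2Q2P1 and PDXDC2P-NPIPB14P belong to families of close copies, where reads are hard to assign to 1 copy.

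On the cytoplasmic side COX7C had 10 windows of nuclear and 68 of cytoplasmic proteins (log2 fold -4.93, SE 0.92, edgeR adjusted p = 0.000566), but the fold was -3.43 with TMM and -3.42 with DESeq2, and the ratio of pooled windows 11.5 (5.91 to 25.2). CHST2 (-4.74), TUBA1A (-4.37), CHCHD10 (-4.35), NUDT4B (-4.34), TOP2B:MIR4442 (-4.27), HBZ (-4.21) and MAGEC2 (-4.15) were also named, with edgeR adjusted p between 0.000526 (CHST2) and 0.00172 (TOP2B:MIR4442). With TMM these folds were smaller, from -2.86 (TOP2B:MIR4442) to -3.97 (NUDT4B), and the ratios of pooled windows ran from 7.13 (TOP2B:MIR4442) to 31.0 (NUDT4B). TOP2B:MIR4442 lost its call with DESeq2 (adjusted p = 0.0652) and HBZ on reads in place of windows (edgeR adjusted p = 0.0599). With 2 or 3 nuclear windows, the ratios of pooled windows were 42.4 (11.2 to 360) for LAGE3, 34.8 (9.04 to 297) for MRPS12, 33.95 (11.1 to 169) for VKORC1 and 33.95 (8.80 to 290) for LGALS1; DESeq2 gave no adjusted p for LGALS1 and MRPS12. NUDT4B is a copy of NUDT4, and the windows of TOP2B:MIR4442 lie where both genes overlap. COX7C and HBZ had windows of 15 and 14 of the 19 cytoplasmic proteins.

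Among the fixed lists, OXPHOS and histone genes had the most calls, and the lists were not tested against each other. Over all 10290 genes tested, 1203 were called higher with cytoplasmic proteins, and 719 with TMM. Of OXPHOS genes, 45 of 82 tested were called higher with cytoplasmic proteins and 0 with nuclear (50 adjusted over the list alone; 24 with TMM). Histone genes followed with 20 of 54 (40 adjusted over the list alone; 10 with TMM), translation factors with 16 of 75 (23; 8 with TMM), ribosomal proteins with 12 of 88 (11; 4), snoRNAs and host genes with 10 of 32 (11; 5) and the proteasome with 8 of 48 (8; 4), where the values in brackets are again adjusted over the list alone and with TMM. No member of these lists was called for nuclear proteins over all genes, whereas TMM called 1 translation factor for them. Ribosomal proteins were called for cytoplasmic proteins at about the share of all genes, and with TMM below it. The proteasome was near that share with TMM. Lists mixed in direction were the erythroid genes, with 2 called for nuclear and 5 for cytoplasmic proteins of 27, and the splicing regulators, with 1 and 4 of 66. Among the leading list members, SNHG16 (log2 fold -3.31, edgeR adjusted p = 0.00143), APOE (-3.23, 0.00823), GAS5 (-2.71, 0.0171), SNHG29 (-2.50, 0.0104), H2BC21 (-2.42, 0.0143), MYC (-2.32, 0.0181), PSMB2 (-1.95, 0.0292) and PSMA4 (-1.79, 0.0475) passed by themselves, and ATP5F1A (-1.73, 0.0621), ATF4 (-1.75, 0.0713) and NDUFS7 (-1.14, 0.225) did not.

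Repeat experiments of a protein shared most or much of the smaller window set. The PTBP1 experiments had 122914 windows in common, 68.4% of the smaller set and 4.18 times the number expected; those of TIAL1 had 15440 in common, 52.7% and 10.4 times. By the ratio of shared to expected windows, which favours small sets, these pairs ranked 592 (PTBP1) and 287 (TIAL1) of 1485 pairs of experiments. By the Jaccard index, which does not divide by expectation and favours large sets of similar size, they ranked 1 and 45. The PTBP1 sets, with 183924 and 179786 windows, are large and similar in size.

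The 18 pairs of related proteins, which include complex subunits, paralogues and looser relations, on average shared more windows than proteins paired at random. EIF2S1 and EIF2S2 of eIF2 shared 261 windows, 591 times the number expected, NCL and NOP2 of the nucleolus 168 times, EIF3B and EIF3C 3271 windows or 133 times, and the synthetases KARS and LARS 119 times. FUS and TAF15 shared 6999 windows (16.3 times), RBM5 and RBM10 14065 (13.1 times), LARP1 and PABPC1 19289 (12.7 times) and UBAP2L and USP10 35795 (8.22 times). Some pairs ranked low among all 1378: EIF4G2 and EIF4H (2.91 times, rank 732), NCBP1 and THOC4 (2.75 times, 759), KHSRP and FUBP3 (1.53 times, 986) and CDC40 and USP39 (0.243 times, 1339). Part of the overlap goes with the region type in common: with expectation taken within region types, EIF3B and EIF3C moved from rank 29 to 364, LARP1 and PABPC1 from 232 to 426 and UBAP2L and USP10 from 339 to 800. Over the 18 pairs the mean log2 ratio was 3.89 (SD 2.82) against 1.79 with protein labels permuted, a 4.31-fold excess (permutation p = 1e-05, the smallest that the permutations can give), and within region types the log2 excess was 1.00 (permutation p = 0.00547). The pair highest of all was not among the related ones: EIF2S2 and NCL, 605 times expected. The ratio favours small sets, and permuting labels does not hold set size fixed, so set size may add to the excess. EIF2S1 (650 windows) and LARS (615), not a related pair, shared 497 times the number expected.

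Many proteins had windows on their own transcript. PABPC1 was the leading gene of the PABPC1 experiment, with 29 windows and 2.68% of reads; CELF1 had 75 windows on its own gene, mainly in the 3' UTR, UBAP2L 51, IGF2BP1 42, and RBM15 34, of which 29 in coding sequence. In all, 38 of 53 proteins had at least 1 window on their own gene, against 29.6 expected when protein labels were permuted (permutation p = 0.0004).

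Noncoding RNAs took large read shares in a few experiments. MALAT1 held 26.0% of the immunoprecipitation reads of the m6A reader YTHDC1 and 17.3% of DDX5, against a median of 0.789% over all experiments, and NEAT1 held 9.28% of PSMD4 and 6.71% of WDR77. The snRNA list took 24.1% of the reads of TAF15, 19.2% of RBM5 and 9.36% of RBM10. Mitochondrial transcripts took 38.2% of PRKRA, 26.9% of the mitochondrial protein TFAM and 19.4% of QKI, and snoRNAs 12.5% of EIF2S2, 11.7% of NCL and 10.3% of EIF3C. XIST stayed at or below 0.582% (PTBP1), and RN7SK had windows in 7 of 56 experiments. These are values without a test.

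Ribosomal RNA was the leading target of many experiments. The gene that spans the ribosomal DNA repeats, ENSG00000280441, held most reads in 27 of 56 experiments; MALAT1 led 9, GSE1 5, CCDC200 3 and LARP4 2. Ribosomal DNA windows occurred in 50 of 56 experiments and held over 50% of reads in 11: NOP2 (93.6%), EIF2S1 (88.4%), NCBP1 (85.0%), EIF2S2 (81.9%), NCL (80.2%), EIF2B4 (78.2%), EIF1 (69.4%), EIF3B (61.5%), GFPT1 (61.3%), EIF3C (54.7%) and DNAJC2 (52.1%). The part of the repeat differed between proteins. 18S rRNA made up 99.1% of the ribosomal reads of EIF3B and 98.6% of UBAP2L, 28S rRNA 77.0% of NCBP1 and 68.7% of NOP2, and the transcribed spacers 86.7% of PRKRA and 22.0% of NCL.

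**Figure D5:**
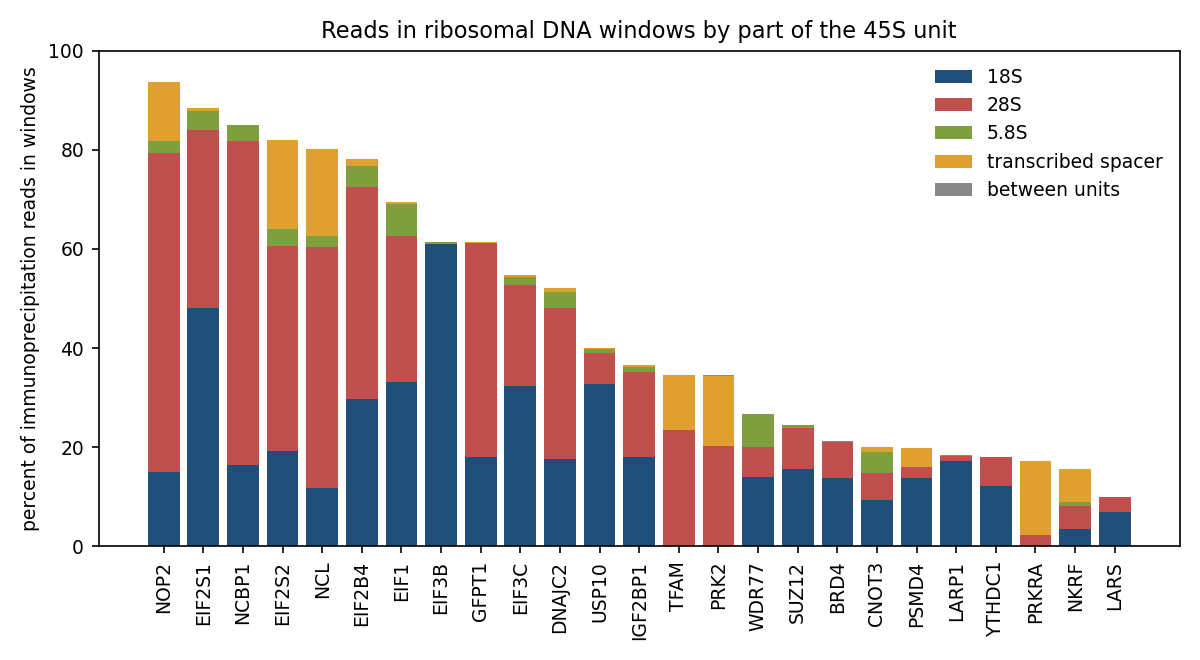
Immunoprecipitation reads in each part of the ribosomal DNA repeats, by experiment.

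Some leading genes recurred between experiments. CCDC200 led for RBM5 (30.5% of reads), RBM10 (10.6%) and CDC40 (4.78%), GSE1 for FUS (10.7%), USP39 (10.2%), YTHDF2 (5.94%) and SFPQ (5.71%) and THOC4 (0.926%), and LARP4 for both PTBP1 experiments (1.41% and 2.29%). CROCC led for TAF15 (13.6%), ENSG00000275016 for KARS (17.0%) and MT-RNR2 for QKI (8.34%). Windows named for both CCDC200 and the snRNA U2 lie within the CCDC200 span. They held 6.37% of reads for RBM5, 2.22% for RBM10 and 1.00% for CDC40. The snRNA RNVU1-7 followed CROCC for TAF15, at 11.4%. Whether reads given to CCDC200 or CROCC come from snRNA copies was not tested. Of the 1123453 distinct K562 windows, 48.0% were found in 1 experiment, 50.3% in 2 to 10 and 1.66% in 11 to 30, and 109 windows in more than 30. The most recurrent, in 49 experiments, were windows of ENSG00000230021 on chromosome 1 (629507 to 629599 and 630831 to 630930).

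Marker genes of the cell lines separate them only weakly in these tables. The globin gene HBG2 had windows in all 15 nuclear and all 19 cytoplasmic proteins of K562. In HepG2, the CDK9 experiment had 0 windows in erythroid genes and 1 in the hepatocyte list (0.106% of its windows), and IGF2 held 18.2% of its reads. That experiment has 943 windows; TFAM in K562, with 882, also had 0 erythroid windows, and 8 of the 19 cytoplasmic proteins of K562 had windows in the hepatocyte list.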

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

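The values tested here beyond the region shares (numbers of windows and ribosomal DNA reads) and the comparison of 7SK between lines were chosen after the data were seen.

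In 3 classes of 4 to 10 proteins, a highest or lowest value far from the rest by Dixon's test was looked for. These were the initiation factors, the other cytoplasmic mRNA proteins and the AU- or U-rich binders, and the 10 proteins classed as others were not tested. Among 21 combinations of class and value 6 were found, all of them highest values. Chance gives about 1 in 20 groups for normally distributed values only. Shares and window numbers cannot fall below 0, and the shares of a protein depend on each other. How far 6 exceeds chance is therefore not measured here. Among initiation factors, EIF2S2 had the highest noncoding exon share, 32.4% against 13.7% for the next protein, and EIF4G2 the most windows, 120167 against 45553. Among the other cytoplasmic mRNA proteins, LARP1, which binds the start of TOP mRNAs, had the highest 5' UTR share, 12.5% against 4.90%. Among the 4 AU- or U-rich binders, TIAL1 was highest in the 5' UTR, at 3.21% against 0.708%, a mean of 1.01% and 5.40% in its separate experiments that rests on the higher of them. KHSRP had the most windows, 201118 against 47623, and CELF1 had the highest share of reads in ribosomal DNA, 0.349% against 0.00440%. No explanation was tested for these values.

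The CDK9 experiment in HepG2 cells entered no comparison and carries a strong signal on 7SK, the RNA scaffold of the complex that holds CDK9 inactive. RN7SK held 8.83% of its immunoprecipitation reads in 1 window, and the list of 7SK, 7SL and similar RNAs 17.7% in 10 windows. The highest RN7SK share in a K562 experiment was 1.94% (EIF2B5). CDK9 in K562 and other proteins in HepG2 were not analysed here, so the effects of line and protein are not separated, and the difference was not tested.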

How the results depend on the processing

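Chosen after seeing the data were the alternatives without ribosomal DNA, without YTHDF2, PDCD4 and CNOT3, and with the older edgeR quasi-dispersion; the rest were fixed before. No paired analysis was possible because the tables sum the reads of each experiment over its replicates and do not say which replicate had the lowest or highest enrichment, so leaving out a replicate or blocking by replicate was not run; leaving out proteins in turn took its place. The motif test and its alternatives were not run, as the genome sequence was not used here. Experiments with few windows limit most values: at the yield of LARS or EIF2S1, a gene without windows says little. Causes were not tested except where stated.

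Differences of region shares (nuclear minus cytoplasmic, percentage points) kept direction and side of the threshold in 48 of 59 cases. The 3' UTR call ended with q under 0.05 (-13.0, adjusted p = 0.0715), log2 enrichment of 2 or more (-13.6, 0.0658), no windows found in more than 10 experiments (-12.4, 0.0864), read weighting (-9.19, 0.220), read weighting without ribosomal DNA (-10.9, 0.129) and without UPF1 (-10.6, 0.0546). Read weighting also ended the intron call (8.81, 0.502) and reversed noncoding exons (7.60, and 0.714 without ribosomal DNA, neither called). The 5' UTR passed without YTHDF2, PDCD4 and CNOT3 (-16.7, 0.0344) and without NCBP1 (-15.8, 0.0381). Without each protein in turn, the 5' UTR ran from -15.8 to -11.0 and the 3' UTR from -14.2 to -10.6.

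For initiation factors minus other cytoplasmic mRNA proteins, 45 of 53 cases were the same. Read weighting ended the calls for the 5' UTR (7.23, and 14.8 without ribosomal DNA) and noncoding exons (3.13, and 17.99) and reversed introns (14.4, not called). Ribosomal DNA windows, with 88.4% of the reads of EIF2S1 and 81.9% of EIF2S2, enter these weighted shares by their deposited feature type. Noncoding exons also lost the call with at least 1000 windows (3.23, exact permutation, adjusted p = 0.0656), where EIF2S1 and EIF2S2 drop out. The 3' UTR passed with CDS and UTR windows as denominator (-24.5) and without EIF4G2 (-21.7; -14.1 at the other end of leaving proteins out).

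Of the 19 lists, 3 passed; the number was 1 with read weighting (translation factors, adjusted p = 0.126, and the stress-response list, 0.273, lost the call; the stress-response list also with q under 0.05, 0.0718, and translation factors with exonic windows, 0.0771), 6 with at least 1000 windows, 6 with each experiment on its own and up to 8 without CNOT3. OXPHOS passed throughout these alternatives. Lists that were never called reversed as follows: snRNA with q under 0.05 (0.0660), without recurrent windows (0.0636), read weighting (3.65), at least 1000 windows (0.0819) and exonic windows (0.160); nuclear long noncoding RNA with q under 0.05 (0.240), read weighting (5.21) and exonic windows (1.46); splicing regulators without recurrent windows (0.0898), read weighting (0.209) and exonic windows (0.704); erythroid genes with log2 enrichment of 2 or more (-0.00804), read weighting (-0.0537) and exonic windows (-0.0272); mitochondrial transcripts with read weighting (0.631); and the tRNA list with exonic windows (-4.42e-05).

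Of genes, 1640 were called, 437 of them (26.6%) for nuclear proteins. The count was 299 with DESeq2 (197 nuclear, 102 cytoplasmic; 65.9% nuclear), 794 with reads (346 cytoplasmic; 56.4%), 1059 with exonic windows (641 cytoplasmic; 39.5%) and 2564 without YTHDF2, PDCD4 and CNOT3 (741 and 1823). With TMM it was 663 and 719 (48.0%), and with the older quasi-dispersion 630 and 1606. Thinned to 500 windows, 173 genes could be tested and edgeR called 0 and 0, a total of 0, with 21 at an unadjusted p under 0.05; no other tool was run on these. Leaving out a protein gave 1264 (PABPC1) to 1934 (CNOT3) genes, with 280 (PTBP1) to 544 (CNOT3) nuclear. No gene was called in opposite directions in any of these. Among the named genes 225 of the 228 cases with an adjusted p were the same; ENSG00000286163 (DESeq2 adjusted p = 0.183), TOP2B:MIR4442 (DESeq2, 0.0652) and HBZ (reads, edgeR adjusted p = 0.0599) lost the call. DESeq2 gave no adjusted p, and so no call, for PURPL, PDXDC2P-NPIPB14P, TPTE2P2, SRGAP2D, L3HYPDH, LGALS1 and MRPS12, whose fold kept its direction; 5 named genes could not be tested with exonic windows and none of the 24 after thinning. The median log2 fold of all genes moved from -0.32 to -0.04 (TMM), 0.08 (DESeq2) and 0.14 (reads).

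The ranks of the repeat pairs of PTBP1 and TIAL1 moved from 592 and 287 to 692 and 592 by gene, 1 and 45 by Jaccard index, 492 and 230 with q under 0.05, 697 and 319 with expectation within region types, 342 and 153 without recurrent windows and 599 and 288 without ribosomal DNA. The excess of related pairs stayed above 0 and called in all 6 alternatives, and so did own-gene windows in all 3.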

Other observations

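The ribosomal RNA tests were chosen after the result was seen, and so was the use, as tests of the patterns below, of the planned settings with TMM, exonic windows, a log2 enrichment of 2 or more and without recurrent windows.

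Proteins outside the contrasts also had distinct profiles. FUBP3 had 45.1% of its windows in the 3' UTR, the enzyme BCAT2 80.1% in coding sequence and the nucleolar protein NCL 32.5% in noncoding exons. PSMD4 and WDR77, of no known complex in common on the lists used here, shared 826 windows, 424 times the number expected. In the authors' deposited table the most enriched window was the same in several experiments: an intronic window of BTBD2 (chromosome 19, 1998553 to 1998650) led 8 of the 23 experiments ranked, with a mean log2 enrichment from 8.47 (TAF15) to 12.79 (PABPC1). It was found in 26 experiments, with 0 input reads in 17. An intronic window of PRTFDC1 (chromosome 10, 24889234 to 24889333) led 3 experiments and was found in 18.

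Ribosomal RNA held over 50% of reads in 11 experiments. A single background profile common to all experiments is argued against: among the 21 experiments with at least 10% of reads there and windows of both 18S and 28S, the share of 18S in the reads of both spanned 75.3 percentage points, from 18.9% (NOP2) to 94.3% (LARP1). The span rests on its extremes and does not cover a background common to only part of the experiments. The share counts reads in enriched windows only, so it also moves with which windows were found. Whether a low yield of other windows contributes stays open: the ribosomal percent fell with the number of windows over 55 K562 experiments (Spearman's rho -0.604, permutation p = 1e-05, the smallest the permutations can give), but reads in other windows are part of its denominator, so a negative value is expected and decides nothing. Contact of initiation and cytoplasmic mRNA proteins with the small subunit stays open too. In the same 21 experiments their 18S share was 59.7% ± 19.6% (9 proteins) against 49.2% ± 23.7% (12 others), a difference of 10.6 points (permutation p = 0.288). The difference of 24.4 points over all 25 experiments with at least 10% (permutation p = 0.0366) includes 4 where a part without windows sets the share to 0% (PRK2, PRKRA, TFAM) or 100% (EIF3B), and is not used.

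YTHDF2, PDCD4 and CNOT3 are cytoplasmic by class but left most windows in introns, against a median of 15.8% over the 9 cytoplasmic mRNA proteins. Windows found in more than 10 experiments do not account for it in CNOT3 (74.1% in introns without them). For PDCD4 (80.4%) and YTHDF2 (71.0%) the share did not fall, but leaving them out could not decide. PDCD4 has 21790 intron windows and YTHDF2 59863. Only 18677 windows were found in 11 to 30 experiments and 109 in more. Removing all of these could not have brought PDCD4 or YTHDF2 down to the median of 15.8%. Windows of 2 to 10 experiments were kept, so sharing at that level was not covered. Weakly enriched windows do not account for it, since at a log2 enrichment of 2 or more the lowest of the 3 was 73.5%. Nuclear RNA carried along could be a source: 86.5% of the intron windows of PDCD4 and 79.5% of those of YTHDF2 were also windows of SFPQ, FUS or USP39, but only 34.6% for CNOT3, with 21.5% expected. That keeps it open. The other 6 cytoplasmic mRNA proteins shared from 25.5% (IGF2BP1) to 76.3% (UBAP2L). A nuclear pool of these proteins cannot be told apart from such RNA here, and was not tested.

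For the gene test, chance is argued against: 1 of 100 splits of the 34 proteins into groups of 15 and 19, the real one, gave as many genes. It called 1640, against 254 in the highest of the others. The median of the others was 2 genes, and 21 of them called no gene. A share of 1 in 100 is the smallest that this number of splits can give. Intron length as the whole reason is argued against only for calls with enough exonic windows to be tested, 327 of 437 nuclear and 1168 of 1203 cytoplasmic. In these, the median log2 fold with exonic windows alone, relative to all genes, was 94.2% (nuclear) and 87.4% (cytoplasmic) of that with all windows. For the calls with too few exonic windows it stays open. The calls were made on counts that include the exonic windows, which favours a kept fold. This comparison of medians was chosen after the number of calls kept had been seen. With exonic windows 57.2% of the nuclear calls that could be tested (187 of 327) and 45.3% of the cytoplasmic (529 of 1168) were called again; 320 and 1163 kept their direction. Scaling by total windows does not explain the 59.7% (718 of 1203) of cytoplasmic calls that were called the same way with TMM. DESeq2 with its own size factors called only 102 cytoplasmic and 197 nuclear genes. Its test differs as well, so it cannot separate scaling from the test. All 1203 kept their direction with TMM, at a median log2 fold of -2.19 against -2.66. Whether the remaining calls pass only because of scaling stays open. A preference of cytoplasmic proteins for short, abundant mRNAs stays open too, since expression was not measured here.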
